A study of Danio rerio with 3 samples.

How the data were processed

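The series holds 3 arrays of brain RNA from adult zebrafish, 1 each for naive, fear-conditioned and sleep-deprived fish, and samples were assigned to these 3 groups from their labels. Per the labels' protocols, total RNA was extracted with Trizol, and fragmented sense cDNA was labelled with biotin by the GeneChip WT terminal labelling kit. Only the table of values deposited by the authors was used. It holds 1 value per probe set and array, and these deposited values are read here as log2 signals, because they run from 0.61 to 13.4 as log2 of a scanner signal would; the base of the logarithm is not stated. The authors had normalized the arrays against each other, as seen from the median of 4.99 on each of the 3 arrays, with lower quartiles of 3.45 for naive, 3.43 for fear-conditioned and 3.49 for sleep-deprived; the method is not given in the sources used here. An unknown normalization of this kind makes the arrays alike in their overall distribution, so a shift of all genes in one direction cannot be seen. Exactly equal values were common: 42.2% of probe sets had the same value on the sleep-deprived and naive arrays, 43.3% on fear-conditioned and naive, 40.2% on sleep-deprived and fear-conditioned, and 33.3% on all 3 arrays. Such ties pull the medians of gene lists to 0, and for that reason means are given beside medians where only 1 of them stands apart from random lists.

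Gene names came from the platform's annotation, which can be old. Of 75212 probe sets, 20806 had 1 gene symbol, 855 had several and 53551 were unnamed in the annotation used here. Probe sets with several symbols were not used. Symbols were brought up to date through Entrez identifiers with a RefSeq gene table of assembly GRCz12tu for 20323 probe sets, and 483 kept the annotation's symbol. No genome build is given for the array in the sources used here, so no coordinates are printed. Probe sets of the same gene were averaged, which gave 19260 genes. A gene was kept when its highest array reached 3.45, the lower quartile of all values. This dim limit is not a measured background. It left out 1302 genes and kept 17958, 1275 of them with more than 1 probe set.

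For each of the 3 comparisons the log2 difference of the 2 arrays was taken as deposited, and genes were counted at a 2-fold threshold, which is a log2 difference of 1. With 1 array per group there is no test, no standard error and no p-value. Gene lists were fixed before the data were examined: 38 lists of pathways and cell types, 37 of which had at least 5 measured members. The median of each list was placed among the medians of 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean expression, and tied medians counted as lying in the middle. A list is called outside when it lies among the lowest 2.5% or the highest 2.5%. These percentiles describe the 3 arrays and are not p-values. With untied medians and genes that vary independently, chance alone would put 1.85 of 37 lists outside in each comparison. Ties at 0 make this number only a rough guide here. Genes of 1 list can also move together between 2 single arrays, so an excess over 1.85 is no measure of treatment effects. The third comparison is the difference of the other 2, so its number is not independent of theirs. Observed were 17 in sleep-deprived over naive, 12 in fear-conditioned over naive and 17 in sleep-deprived over fear-conditioned. Of these, 15, 9 and 15 were outside by the mean as well.

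Named genes followed a rule set before the data were examined: in each comparison the 10 genes with the most positive and the 10 with the most negative difference, without clone or locus names; up to 4 members of each described list with the largest difference in size; all clock repressors and activators in sleep-deprived over naive; and fosab, npas4a, egr1, bdnf, hcrt, aanat2, crhb, pomca, nr3c1 and fkbp5 in both comparisons with naive. Alternatives set before the data were examined were centring each array on its median, quantile normalization, removal of a lowess trend on expression level (fraction 0.3), the brightest probe set in place of the mean, no filter on dim genes, a filter at the median of all values (4.99), a 1.5-fold threshold, 5 expression bins and the list mean in place of the median. Added after the data were seen were counts without genes of other tissues, counts with values below the dim limit set to it, skin and fibroblast lists without their members at least 2-fold apart, and 4 further gene lists. The counting and list steps were tested on simulated data with the mean levels of 17958 genes over the 3 arrays, compared as sleep-deprived over naive. In them, 100% of 200 genes changed 3-fold were recovered and 0 unchanged genes were called. Of 400 lists of 30 genes drawn at random, which could hold changed genes, 4.25% lay outside. A list shifted by 0.3 lay at percentile 100, but that shift is larger than most list medians given below. That simulation assumed normal noise with an SD of 0.122 per array, taken from all 3 comparisons, and held no tied values. Such noise is small against the 2-fold threshold, so the simulation checks the steps and not the rate of false calls in the real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.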

Results

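Gene expression was measured in the brain of adult zebrafish, 6 months old and kept at 28 °C, under 3 conditions. Naive fish lived in 14 h of light and 10 h of dark per day. Sleep deprivation was produced with 3 days of extended light, 24 h of light and 0 h of dark per day. Fear-conditioned fish had gone through inhibitory avoidance learning, a task in which an animal learns to withhold a response that leads to an aversive stimulus. Their hours of light are not given in the sources used here, and a light-dark tag stands in the labels of all 3 groups, the sleep-deprived one included. Each condition was measured on 1 array, so no difference given here has a replicate check, and all values describe these 3 arrays. Whether the RNA of an array came from a single fish or a pool, and at what time of day fish were sampled, is not given in the sources used here. After dim genes were left out, 17958 named genes entered the comparisons. Across genes, which are not independent replicates, Pearson's r between arrays was 0.991 for sleep-deprived and naive, 0.994 for fear-conditioned and naive, and 0.990 for sleep-deprived and fear-conditioned. The number of arrays limits the precision.

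The first comparison asked how gene expression in the brain after sleep deprivation by extended light differed from that of naive fish. Among named genes, 120 were at least 2-fold lower on the sleep-deprived array and 17 at least 2-fold higher. Probe sets with no gene name had the other balance, with 628 lower and 829 higher of 37914. Immediate early genes, which are transcribed within minutes of neuronal activity or cell stimulation, were lower, with a median log2 difference of -0.29 over 40 genes. Genes of microglia and macrophages had a median of -0.50 over 35 genes, and interferon response genes a median of -0.27 over 36. Higher on the sleep-deprived array were genes of photoreceptors and the pineal organ, with a median of 0.11 over 35 genes, glutamate receptors (0.13 over 35) and genes of GABA and glycine signalling (0.11 over 35).

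Of the 40 immediate early genes, 8 were at least 2-fold lower and 0 at least 2-fold higher, and the list median lay at percentile 0 of 10000 random lists matched on expression. The log2 difference was -1.60 for nr4a1, -1.41 for csrnp1a, -1.31 for dusp2, a phosphatase that acts on MAP kinases, and -1.26 for npas4a, a transcription factor induced by depolarization. The transcription factor fosab was also lower, at -1.25. In contrast, egr1 had a log2 difference of 0.10, and bdnf, a neurotrophin gene, one of -0.12.

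Among 35 genes of microglia and macrophages, 3 were at least 2-fold lower, 13 at least 1.5-fold lower and 0 at least 1.5-fold higher (percentile 0). They included a progranulin gene, grna.1 (-1.67), lgals3bp.1 (-1.30), the apolipoprotein gene apoeb (-1.09) and the cathepsin gene ctsba (-0.97). With the brighter of its probe sets alone, apoeb was at -0.95, short of 2-fold. In the interferon response list (percentile 0), isg15, a ubiquitin-like modifier, had a log2 difference of -2.01 and the transcription factor irf7 one of -1.69, whereas the MHC class I gene mhc1uba was higher, at 1.37. The p53 and DNA damage list had a median of -0.16 over 23 genes (percentile 0) with 0 genes at least 1.5-fold lower. The inflammation list had a median of -0.05 over 36 genes (percentile 0.010), with socs3a, an inhibitor of cytokine signalling, at -1.89.

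Markers of several other cell types were lower on the same array. The median was -0.15 over 36 skin and epithelium genes (percentile 0), -0.10 over 21 oligodendrocyte genes (percentile 0.12) and -0.09 over 31 genes of radial astroglia (percentile 0.15). By its mean, the oligodendrocyte list was not outside the central 95% of random lists (percentile 4.32). In radial astroglia, nes, which encodes the intermediate filament nestin, was at -2.36, gfap at -0.91 and the brain aromatase cyp19a1b at -0.87. The neuron list had a median of 0.02 over 26 genes, at percentile 98.6. Ribosomal protein genes had a median of -0.08 over 65 genes (percentile 0), with 1 of them at least 1.5-fold lower. For blood cell genes the median was -0.02 (percentile 0.79) and for endothelium and mural cells -0.01 (percentile 0.52), and centring each array on its median over named genes, which adds the same amount to every difference and leaves the percentiles as they are, turned both signs, to 0.02 and 0.04. The same holds for the antioxidant list, whose median of -0.01 (percentile 1.19) became 0.03 with centring, although nfe2l2b and nfe2l2a, which encode Nrf2 transcription factors, were at -1.40 and -1.06. The list means lay further from 0. They were -0.24 for blood cells (percentile 0.010), -0.16 for endothelium and mural cells (percentile 0.22) and -0.15 for the antioxidant list (percentile 0.71). The blood cell mean includes nt5c2l1 at -2.53 and epb41b at -1.13.

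Several genes of glucose uptake and glycolysis were among those with large negative differences. The kinase gene pfkfb3, whose product makes an activator of glycolysis, was at -2.33, the glucose transporter genes slc2a3b and slc2a1b at -1.28 and -1.02, and the hexokinase gene hk2 at -0.98. With centring, slc2a1b was at -0.98, short of 2-fold. The list as a whole had a median of -0.01 over 39 genes, at percentile 3.12 and so inside the central 95% of random lists, but a mean of -0.23 at percentile 0.010. The median was outside with a dim filter at the median of all values (percentile 1.25) and with 5 expression bins (percentile 2.11).

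In the photoreceptor and pineal list (percentile 100), 2 of 35 genes were at least 2-fold higher and 4 at least 1.5-fold higher. They were led by exorh, which encodes the opsin of the pineal organ, at 1.302, and pde6gb, a subunit of the photoreceptor phosphodiesterase, at 1.04, followed by rbp4l (0.81) and the arrestin gene saga (0.70). The melatonin synthesis gene aanat2 was at 0.18. Glutamate receptor genes (percentile 100) had differences below 1 in size, with grm7 at 0.66, grm6a at 0.44 and grik2 at 0.32, while grin2ca was at -0.64. GABA and glycine signalling genes (percentile 100) included gabra2b at 0.50 and glra3 at 0.39, and slc6a9, a glycine transporter, at -0.39.

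Circadian clock genes gave no single direction. The clock repressors had a median of 0.02 over 21 genes (percentile 98.4), but a mean of -0.0049 at percentile 75.7, and after quantile normalization the median was at percentile 97.1. Among them, per3 was at 0.73, per1a at 0.54, ciarta at 0.36, bhlhe41 at 0.35, nr1d1 at 0.32, and per1b and nr1d2b both at 0.26. The 3 nfil3 genes were all negative, nfil3-5 at -1.14, nfil3-6 at -0.56 and nfil3 at -0.35, as were nr1d2a (-0.51), cry3b (-0.35) and nr1d4b (-0.28). Differences for ciartb, per2, nr1d4a, cry2, cry1a, cry1b, cry3a and bhlhe40 were 0.12, 0.08, 0.05, 0.02, -0.01, 0.00, 0.00 and 0.00. The 16 clock activators had a median of -0.04 (percentile 5.59). The values were -0.65 for rorcb, -0.47 for npas2, -0.25 for tefa, -0.21 for bmal1a and for bmal1b, -0.10 for clocka and -0.09 for bmal2, and on the other side 0.39 for dbpa, 0.34 for dbpb, 0.19 for rorb and 0.17 for roraa. The remaining activators, hlfb, hlfa, clockb, tefb and rorab, were at -0.07, -0.02, -0.01, 0.00 and 0.04. Light-induced genes (19 genes, percentile 53.4), sleep and arousal neuropeptides (43 genes, percentile 50.2) and the unfolded protein response (33 genes, percentile 52.4) had medians of exactly 0. Within them, the melanin-concentrating hormone gene pmchl was at -1.11 and the pseudokinase gene trib3 at -1.68, and hcrt, the gene of the wake-promoting peptide hypocretin, was at 0.00.

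The stress axis list also had a median of 0 (27 genes, percentile 51.2), and 2 of its genes were at least 2-fold lower, klf9 (-1.25) and fkbp5 (-1.09), both known to be induced by glucocorticoids. The hormone precursor pomca was at 0.00, the releasing hormone crhb at 0.04, the glucocorticoid receptor nr3c1 at -0.04 and oxytocin (oxt) at 0.94. Over all genes, the most negative differences belonged to ociad2 (-2.94), cyp24a1 (-2.85), which inactivates vitamin D, nt5c2l1 (-2.53), rab38c (-2.36), nes, pfkfb3, tspan36 (-2.28), isg15, the transcription factor atf5b (-1.93) and pdk2b (-1.93), a kinase that inhibits pyruvate dehydrogenase. The most positive were s100s (1.63), mhc1uba, exorh, OTOA (1.24), znf1173 (1.22), the sodium pump gene atp1a1a.4 (1.08), ovch1 (1.08), casp8l1 (1.06), and1 (1.04) and pde6gb. The naive signal of znf1173, 2.88, was below the dim limit of 3.45, and with that limit in its place the difference was 0.64, short of 2-fold. On the sleep-deprived array ociad2 was close to the limit, at 3.59, so the size of its difference is uncertain.

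**Figure D1:**
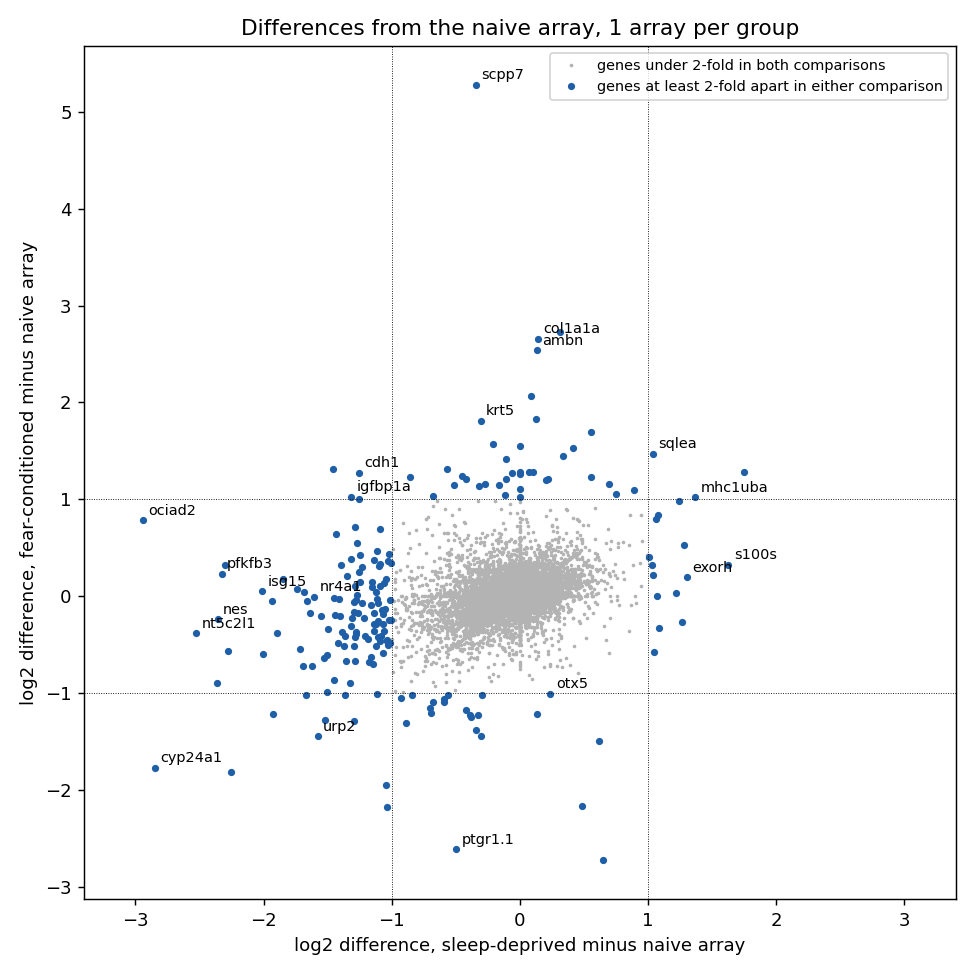
Each point is 1 of 17958 genes, with its log2 difference between the sleep-deprived and the naive array on the horizontal axis and that between the fear-conditioned and the naive array on the vertical axis; dotted lines mark 2-fold. The 120 genes left of the dotted line on the left were at least 2-fold lower on the sleep-deprived array, and scpp7 lies at 5.28 on the vertical axis.

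Fear-conditioned fish were compared with naive fish to find genes whose expression accompanied inhibitory avoidance learning. Here 44 named genes were at least 2-fold higher and 33 at least 2-fold lower, as were 724 and 690 of the unnamed probe sets. Among the genes with the most positive differences, scpp7, a secretory calcium-binding phosphoprotein, was 38.8-fold higher, a size that is uncertain because its naive signal of 3.57 was close to the dim limit of 3.45, col1a1a 6.31-fold, and ambn, which encodes an enamel matrix protein, 5.81-fold. Genes of cholesterol synthesis and of oxidative phosphorylation were higher by smaller amounts, with median log2 differences of 0.16 and 0.13. Microglia and macrophage genes were lower, with a median of -0.25 over 35 genes.

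The skin and epithelium list had a median of 0.25 over 36 genes (percentile 100), with 5 genes at least 2-fold higher, 12 at least 1.5-fold higher and 0 at least 1.5-fold lower. Its members included keratin krt5 at 1.81, the adhesion genes epcam at 1.32 and cdh1 at 1.27, and the plakophilin gene pkp3a at 1.14. The list of meninges and fibroblasts had a median of 0.04 over 27 genes (percentile 99.9) and a mean of 0.34 (percentile 100), and its 3 genes at least 2-fold higher all encode type I collagen: col1a1a at 2.66, col1a2 at 2.07 and col1a1b at 1.83. Skeletal muscle genes had a median of 0 over 37 genes and a mean of 0.18 (percentile 99.9), with the parvalbumin gene pvalb2 at 1.42 and the creatine kinase gene ckma at 1.21. The fear-conditioned signal of pvalb2 was 4.90, so its naive signal was close to the dim limit and the size of its difference is uncertain. Without the genes of these 3 lists and of a bone, cartilage and tooth list, an alternative added after the data were seen, 34 genes were at least 2-fold higher and 33 lower. The added list had 0 genes at least 2-fold higher, as it was written without scpp7, ambn, enam and col10a1a, which are still among the 34.

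Of 25 genes of cholesterol synthesis (percentile 100), 2 were at least 2-fold higher and 0 at least 1.5-fold lower. The squalene epoxidase gene sqlea was at 1.47, hmgcra, which encodes the rate-limiting enzyme of the pathway, at 1.04, cyp51 at 0.66 and msmo1 at 0.56. Nuclear genes of oxidative phosphorylation (percentile 100) numbered 82, of which 3 were at least 1.5-fold higher and 0 at least 1.5-fold lower, among them the complex I genes ndufa9a (0.77) and ndufa6 (0.61). Smaller medians outside the central 95% of random lists were 0.03 for glycolysis (percentile 99.2), 0.03 for ribosomal proteins (percentile 99.8), 0.04 for GABA and glycine signalling (percentile 99.6) and 0.02 for glutamate receptors (percentile 98.2). By the mean, 3 of these were inside: glycolysis (percentile 97.4), GABA and glycine signalling (percentile 78.8) and glutamate receptors (percentile 88.5), the latter also after quantile normalization (percentile 95.3). Ribosomal proteins were inside when the brightest probe set stood for a gene (percentile 93.8). The neuron list had a median of 0.01 over 26 genes (percentile 81.3) and a mean of 0.08, which was outside (percentile 97.9).

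The 48 plasticity kinases and transcription factors had a median of 0 (percentile 43.2) and 0 genes at least 1.5-fold apart, with prkacba at -0.41 and crema at 0.21. Immediate early genes had a median of 0 over 40 genes (percentile 49.3) but a mean of 0.10 (percentile 99.8), with fosl1a at 1.23, klf4 at 0.57, nr4a2b at 0.50, fosab at 0.43, npas4a at -0.17, egr4 at -0.52, and egr1 and bdnf both at 0.00. The clock repressors had a median of 0.04 (percentile 96.3), with nfil3-6 at 0.58, per2 at 0.50, nfil3 at 0.45 and nr1d1 at -0.44. In the stress axis (median 0, percentile 48.1, but 0.06 and percentile 99.8 with a dim filter at the median of all values), oxt was at 0.84, fkbp5 at 0.33, crhb at -0.15, nr3c1 at -0.20 and pomca at 0.00. Both hcrt and aanat2 had a difference of 0.00.

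Among 35 genes of microglia and macrophages (percentile 0), 2 were at least 2-fold lower, the galectin gene lgals9l1 (-1.30) and grna.1 (-1.02), whereas ptprc, the pan-leukocyte marker CD45, was at 0.86. Genes of radial astroglia had a median of -0.07 over 31 genes (percentile 0), with gfap at 0.76 and mfge8a at -0.59. Endothelium and mural cells (median -0.03, percentile 0) included rgs5a at -1.06 and etsrp at 1.28, and with a dim filter at the median of all values the list median was 0. The interferon response list had a median of -0.01 (percentile 0.010) and a mean of -0.13, with mhc1zba at -1.02, mxa at -0.87, irf7 at -0.72 and mhc1uba at 1.02.

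Beyond these lists, the largest positive differences included col10a1a at 2.73, the mucin gene muc5.2 at 1.69, the cytokine gene il11a at 1.57 and the enamel gene enam at 1.55. The 3 probe sets of col10a1a disagreed, with differences from 0.86 to 4.48, and its naive signal of 3.57 was close to the dim limit. Most negative were ptgr1.1 (-2.61), a prostaglandin reductase, traf3ip2l (-2.17), cyp24a1 (-1.77), ggact.3 (-1.49), urp2 (-1.44), a urotensin II related peptide, lgals9l1, lygl2 (-1.28), the membrane receptor gene paqr8 (-1.23), timp4.3 (-1.22) and pdk2b (-1.21). The fear-conditioned signal of ggact.3, 3.28, was below the dim limit, and with the limit in its place the difference was -1.31.

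**Figure D2:**
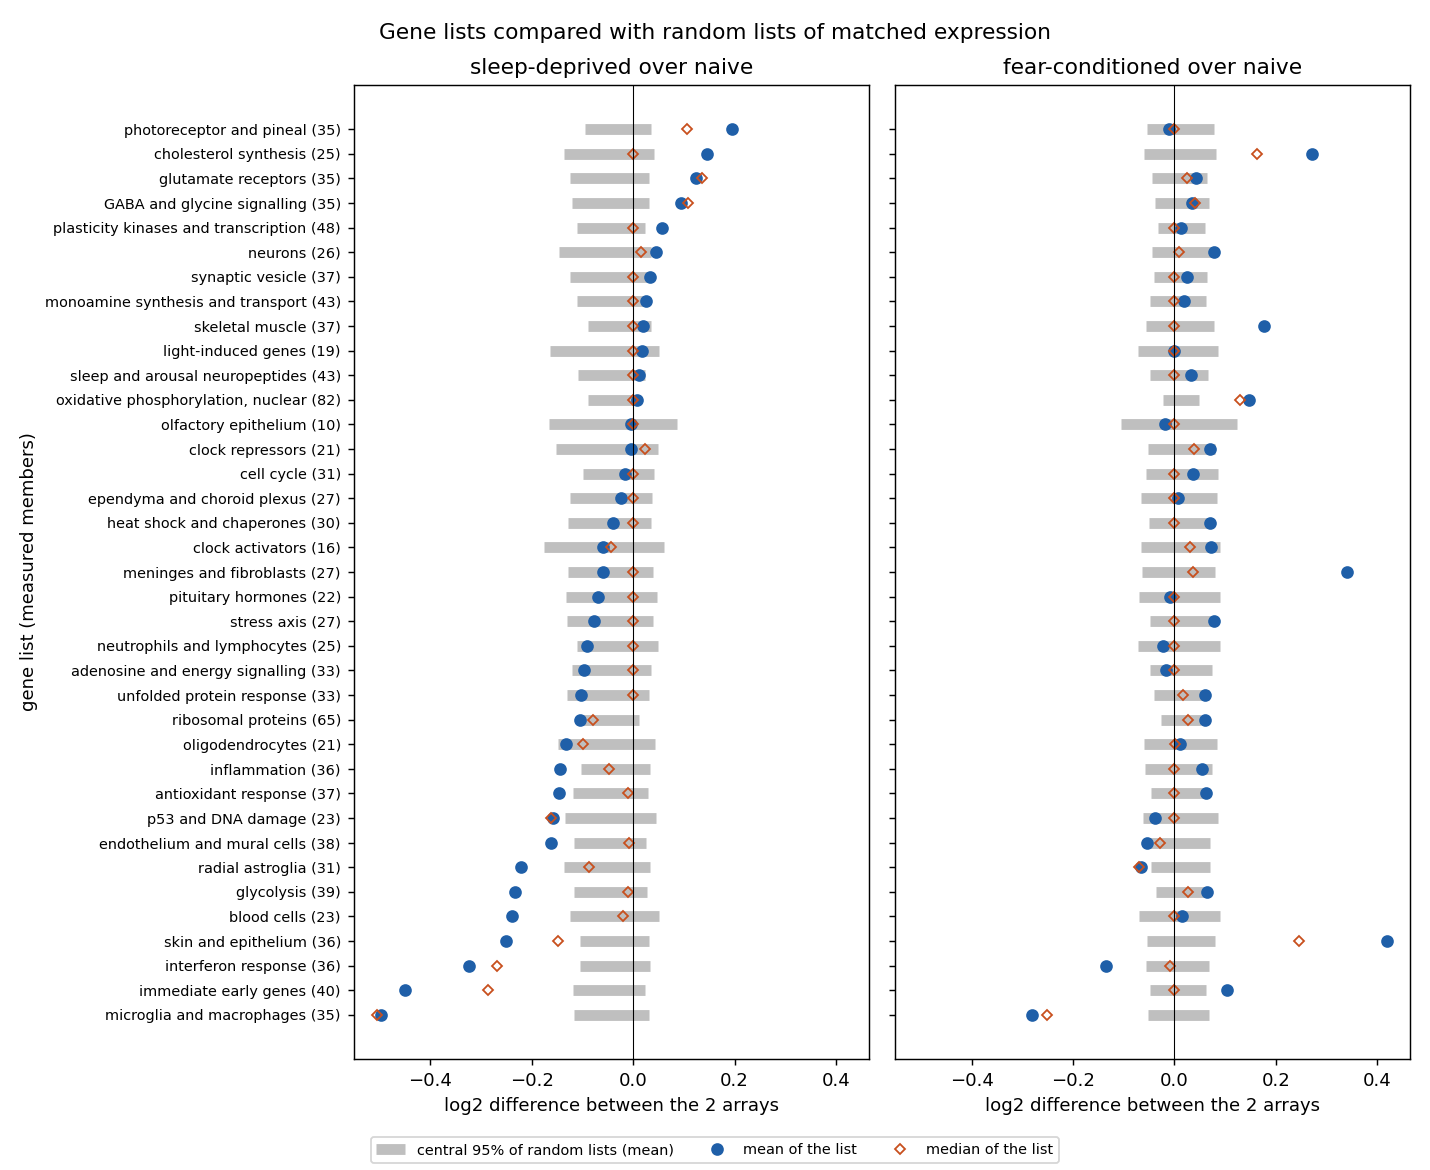
Mean (circles) and median (diamonds) log2 difference of 37 gene lists in both comparisons with the naive array, with the number of measured members in brackets; grey bars span the central 95% of the means of 10000 random lists matched on expression. Microglia and macrophages have the lowest mean in both panels, and skin and epithelium the highest in the right-hand panel.

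The last comparison set sleep-deprived against fear-conditioned fish, both of which had been exposed to a stress. Each of its differences is the first comparison minus the second, so genes higher only on the fear-conditioned array count as lower here. Skin and epithelium genes, for example, had medians of -0.15 in the first comparison and 0.25 in the second. On the sleep-deprived array 156 named genes were at least 2-fold lower and 24 at least 2-fold higher, whereas of the unnamed probe sets 785 were lower and 979 higher. The lists with the lowest medians were skin and epithelium (-0.44 over 36 genes, 10 of them at least 2-fold lower) and immediate early genes (-0.43 over 40 genes, 8 at least 2-fold lower). Photoreceptor and pineal genes had a median of 0.01 over 35 genes and a mean of 0.21, both at percentile 100, with otx5 at 1.25 and exorh at 1.104.

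Among immediate early genes (percentile 0), fosl1a was at -2.09, fosab at -1.68, nr4a1 at -1.60 and the phosphatase gene dusp1 at -1.51. Glycolysis genes had a median of -0.07 over 39 genes (percentile 0.28) and a mean of -0.30, with pfkfb3 at -2.56, slc2a1b at -1.45, slc2a3b at -1.39 and hk2 at -1.13. Nuclear genes of oxidative phosphorylation had a median of -0.12 over 82 genes and ribosomal proteins one of -0.15 over 65 genes, both at percentile 0. Microglia and macrophages had a median of -0.20 (percentile 0), with ptprc at -0.93. Of the stress axis (median 0, percentile 54.7; mean -0.16, percentile 2.07 and so outside), fkbp5 was at -1.43, klf9 at -1.40 and hsd11b2, whose product inactivates cortisol, at -1.02. Centring brought hsd11b2 to -0.97.

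The most negative differences were those of scpp7 (-5.62), ociad2 (-3.72), pfkfb3, cdh1 (-2.53), col1a1a (-2.52), col10a1a (-2.41), ambn (-2.40), igfbp1a (-2.35), mych (-2.26) and nt5c2l1 (-2.15). Some of these differences came from high signals on the fear-conditioned array, 8.07 for col1a1a and 7.24 for ambn. Their naive and sleep-deprived signals were close, at 5.41 and 5.55 for col1a1a and 4.70 and 4.83 for ambn. For col10a1a, the probe sets ranged from -4.30 to -0.52. The most positive were ptgr1.1 (2.11), ggact.3 (2.11), and1 (1.62), atp1a1a.4 (1.41), the chemokine receptor gene ccr2 (1.34), s100s (1.301), nkd3l (1.28), otx5, the ammonium transporter gene rhcgb (1.21) and znf1173 (1.19). In 5 of these genes the lower array was below the dim limit, so sizes and ranks are uncertain. With the limit in its place the differences were -5.39 for scpp7 and 1.93 for ggact.3, while ccr2 (0.76), nkd3l (0.48) and znf1173 (0.64) were short of 2-fold.

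**Figure D3:**
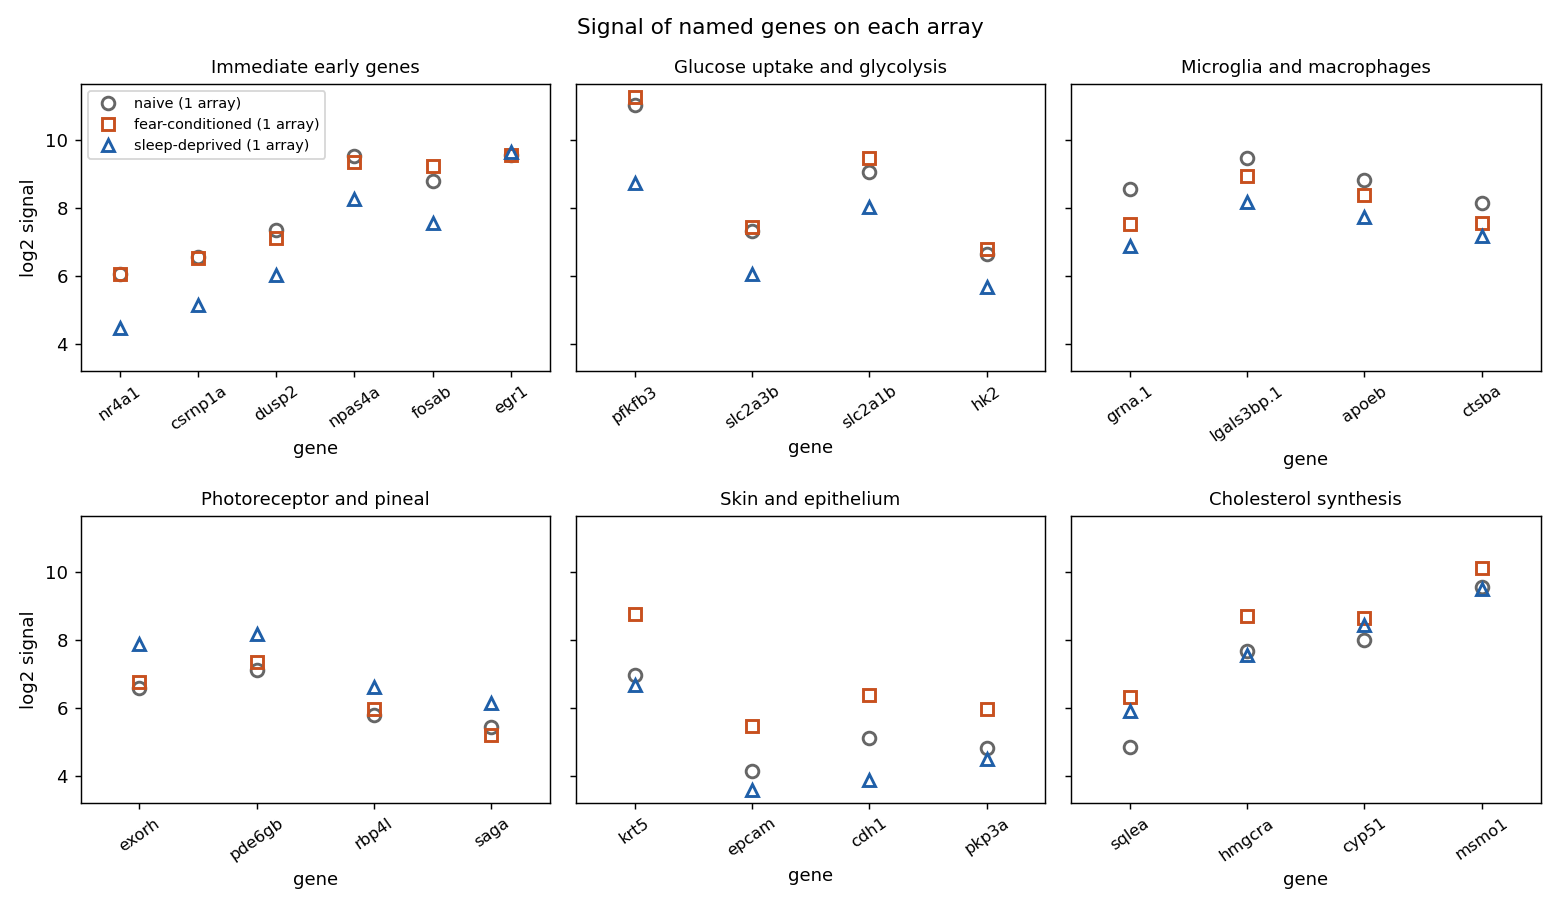
Log2 signal of named genes, grouped by gene list, with 1 symbol per array and gene (circle, naive; square, fear-conditioned; triangle, sleep-deprived). The triangle of pfkfb3 lies at 8.73 and its circle at 11.06, the triangle of exorh at 7.88 and its circle at 6.58, and the square of krt5 at 8.79 and its circle at 6.97.

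Genes that differed from the naive array in both other groups were few. Lower by at least 2-fold in both were 11 genes, including cyp24a1, pdk2b, urp2, traf3ip2l, lygl2 and grna.1, and higher in both were 3, mhc1uba (1.37 in sleep-deprived and 1.02 in fear-conditioned), sqlea (1.04 and 1.47) and LOC100149475 (1.75 and 1.28), which was named after its values were seen. In 4 genes the 2 differences were at least 2-fold in opposite directions: cdh1, igfbp1a, mych and si:dkey-247k7.2 were lower in sleep-deprived and higher in fear-conditioned fish, the last of them named after its values were seen. Of these 4, cdh1 belongs to the skin and epithelium list, whose medians also had opposite signs, -0.15 and 0.25. Both comparisons share the naive array, which by itself makes differences go together. The same limit holds for lists on the same side of 0 in sleep-deprived and fear-conditioned fish. Among them were microglia and macrophages (medians -0.50 and -0.25) and glutamate receptors (0.13 and 0.02). Across genes, the correlation of the 2 differences was 0.305, where 100 simulations of 3 arrays that differ by noise alone gave 0.497. Their covariance was 0.0122, against 0.0235 in the simulations, and the simulations gave 23.1 genes lower and 23.8 higher in both, where independent lists would share 0.22 and 0.042. The simulated values all lie above the observed ones, but they cannot decide how much of the excess over independent lists comes from the shared array. The simulations gave all 3 arrays equal noise per gene, sized from the observed spread of the same arrays, so any effect of treatment counted as noise. With 1 naive array the controls could not be split.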

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

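The tests of outlying skin genes and of an intensity trend were chosen after their results had been seen; the other tests of this part were set before, on lists written once the main results were known. Probe sets with no gene name here stood outside the comparisons and were looked at separately. Whether they hold signal over background was not measured. Of 37914 such probe sets that passed the dim filter, 829 were at least 2-fold higher and 628 lower in sleep-deprived over naive, and 724 higher and 690 lower in fear-conditioned over naive. Of 19294 named probe sets, 21 were higher and 128 lower in the former, and 49 higher and 39 lower in the latter. Their log2 differences had an SD across probe sets of 0.41 and 0.40, against 0.22 and 0.19 for named ones.

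The skin and fibroblast lists were higher on the fear-conditioned array, as were the tooth genes scpp7, ambn and enam, which come from the top of the ranking and belong to no list fixed beforehand. A few outlying genes in the skin list cannot account for all of it, since 27 of its 36 members were above 0, where the central 95% of random lists had 4 to 14 (percentile 100). After removal of an intensity trend the median was again at percentile 100. The random lists were already matched on expression level, so this removal could hardly change the percentile and decides nothing. Tissue from outside the brain remains a candidate explanation: its test on bone, cartilage and tooth genes, without those that led to the idea, gave percentile 50, the outcome set beforehand as speaking against it, but the test was judged void afterwards because the medians of its random lists were all exactly 0 (the mean, examined later, was 0.074, at percentile 97.8). Of the 36 skin genes, 35 were at or above the dim limit on the naive array, 22 were at or above the median, and 0 were in another list. Genes entered by their highest array at that same limit, so the 35 is partly fixed by the filter. The abundant skin genes krt8, cd9b and krt18a.1, named after their values were seen, had differences of -0.05, -0.05 and 0.00 while krt5 was at 1.81. They were picked from a list with 27 members above 0, so they do not weigh against carry-over. The skin list also differed on the sleep-deprived array, in the other direction. Its median over naive was -0.15 (percentile 0), with 26 of 36 members below 0, so differing skin signal was not particular to the fear-conditioned array. With 1 array, carry-over of other tissue and an effect of conditioning cannot be told apart, and conditioning itself was not tested.

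Immediate early genes were lower on the sleep-deprived array, as were klf9 (-1.25) and fkbp5 (-1.09) of the stress axis, a list whose median was 0. A lower glucocorticoid signal at sampling is a candidate explanation: 27 other glucocorticoid-induced genes, of which 0 are in a fixed list, had a median of -0.16, at percentile 0. Less hypoxia between capture and extraction is another, since 23 hypoxia-induced genes outside glycolysis had a median of -0.09, at percentile 0.1, with vegfaa at -1.15 and egln3 at -1.30. A smaller share of non-neuronal cells was left open. The median of 11 neuron-enriched activity genes, 5 of them also in a fixed list, lay at percentile 54.02, which at first counted in favour. But npas4a, which is also among the immediate early genes, was at -1.26 and the mean lay at percentile 4.19, so by a rule added afterwards the test decides nothing. Extended light, lost sleep, the time of day and handling stay open and untested, as each is bound to 1 array.

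Exactly equal values on pairs of arrays, 40.2% to 43.3% of probe sets, may come from a summary by median polish, in which column effects of few arrays often tie. Simulated sets of unchanged probes gave ties in 1.98% of pairs with 4 probes per set and up to 86.1% with 32. The observed shares lie in this range, but so wide a range could hardly miss them. The real number of probes per set was not used here, so the simulation shows only that median polish can produce such ties. Against quantile normalization of the summarized values as the source, the 3 sorted columns were identical at 6.02% of ranks. No biological explanation was tested for these ties.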

How the results depend on the processing

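All alternatives were set before the data were examined, except the counts without genes of other tissues, the counts with values below the dim limit set to it, and the lists without members at least 2-fold apart. At 1.5-fold, the counts were 87 higher and 436 lower in sleep-deprived over naive, 149 and 137 in fear-conditioned over naive, and 101 and 487 in sleep-deprived over fear-conditioned, as the lower threshold takes in more genes; the other 48 of 54 alternative counts were within 1.5 times the main count. Of 890 alternative values of lists, 828 kept their side of the limit, 43 moved outside, 12 moved inside and 7 reversed. Direction was compared only where the main value lay outside, so a value inside in both settings counts as kept whatever its sign. Clock repressors in sleep-deprived over naive moved inside after quantile normalization (0.025) and reversed with the mean (-0.0049), and immediate early genes in fear-conditioned over naive moved outside with the mean (0.10); the cause was not tested. Array medians over named genes differed by -0.04 in sleep-deprived over naive and by -0.05 in sleep-deprived over fear-conditioned, while the median difference per gene was 0. Centring takes these amounts out of every gene alike, which leaves percentiles as they are and says nothing of a list against other genes, but it turned the sign of small medians: antioxidant response to 0.034 and 0.021 in these 2 comparisons, blood cells to 0.023 and 0.036, endothelium and mural cells to 0.037 in the former and interferon response to 0.0075 in the latter. Of 2096 alternative values of single genes, 9 crossed 2-fold, those of apoeb, dio2, hsd11b2, hspb1, kdr, keap1a, npas2, pih1d2 and slc2a1b. The alternative for linear values was not run, since the values are on a log scale. No paired analysis was possible because each group has 1 array and no result comes from a test. Signal over background is not given in the values used here, so dim genes were limited only by the filter.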

Other observations

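Cholesterol synthesis genes had a mean difference of 0.15 over 25 genes in sleep-deprived over naive (percentile 100) and a median of 0, with sqlea at 1.04, cyp51 at 0.45, hmgcs1 at 0.44 and fdft1 at 0.37. On the same array, means of 3 synaptic lists lay above the central 95% of random lists with medians of 0: 0.06 for plasticity kinases and transcription (percentile 99.9; camk2b2 0.52, adcy1a 0.41, shank3a 0.32), 0.03 for the synaptic vesicle (percentile 98.3; unc13a 0.36, syn2a 0.30) and 0.02 for monoamine synthesis and transport (percentile 97.8; drd3 0.59). Medians of 0 and means inside the central 95% were found there for heat shock and chaperones (percentile 52.4), adenosine and energy signalling (50.8), nuclear oxidative phosphorylation (50.2), cell cycle (50.04), neutrophils and lymphocytes (50.2), ependyma and choroid plexus (50.3), meninges and fibroblasts (50.7), pituitary hormones (50.9), skeletal muscle (50.005) and olfactory epithelium (52.2). Single genes among them with a difference of at least 2-fold were hspb1 (-1.01), igfbp1a (-1.32) and dio2 (-1.03), the deiodinase that activates thyroid hormone. By its median, adenosine and energy signalling was outside after quantile normalization (percentile 1.25) and with a dim filter at the median of all values (1.06), and so were neutrophils and lymphocytes with that filter (0.79). With centring hspb1 was at -0.97 and dio2 at -0.99.

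In fear-conditioned over naive, clock activators (percentile 93.2), light-induced genes (47.7), photoreceptor and pineal genes (49.985), the unfolded protein response (96.8), sleep and arousal neuropeptides (49.9), p53 and DNA damage (49.1), antioxidant response (49.3), inflammation (49.985) and oligodendrocytes (92.3) had medians inside the central 95% of random lists. Within them, otx5, a photoreceptor and pineal transcription factor, was at -1.01. Each array's own share of the variance of the differences across genes, taken from their covariances, was 0.0122 for naive, 0.0211 for fear-conditioned and 0.0358 for sleep-deprived.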
